A study of Mus musculus with 8 samples.

How the data were processed

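The data were treated as bulk RNA sequencing of mouse liver in an autoimmune hepatitis model, 4 libraries with albumin-Cre and floxed Bicd2 (Alb-Cre) and 4 with floxed Bicd2 without Cre (Alb-WT). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and made into Illumina libraries. The sample descriptions also say 10x Genomics, a name tied to single-cell kits, which that protocol and a table with a single column for each library do not match. The deposited table gave FPKM, fragment numbers scaled by gene length and library total, as the authors computed it. Per the submitters' processing notes HISAT2 2.0.5 was used, and those notes list a mouse and a human genome build with no role. The counting tool, the annotation, the strand setting and the library total used for scaling are not given in the sources used here. No coordinates are printed, because the reference at hand was of another build.

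The table held 13703 rows for 13696 distinct symbols, 5 of which stood on 12 rows, and repeated rows were kept apart. It held no value of 0, the smallest being 0.0017 FPKM, so genes with no fragment in any library are not analysed here, and a gene switched off in a group would be missing. The steps between FPKM values gave whole fragment numbers for 13695 rows (99.94%, tolerance 1e-08). The gene lengths this implied equalled the merged exon length of the GENCODE M21 annotation within 1 bp for 12576 of 13459 genes (93.4%). The 8 rows not recovered were left out wherever fragments were used. In simulated libraries the recovery was exact for 99.82% of 13686 genes. Recovered fragments over the listed genes came to 27165623, 27534131, 29657003 and 32436571 in Alb-Cre replicates 1 to 4 and 27465288, 31896234, 27234347 and 30347325 in Alb-WT replicates 1 to 4. These were 81.8% to 82.9% of the totals behind the FPKM values. Median FPKM over the rows was 2.15, 2.13, 2.15 and 2.76 in the Alb-Cre and 2.80, 2.73, 2.83 and 2.76 in the Alb-WT libraries. For Bicd2 the recovered fragments ranged from 115 to 741 per library, and genes of few fragments are correspondingly less precise.

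Libraries were compared in pairs before they were averaged. Differences between libraries exceeded counting noise in every pair, with squared deviates 4.90 to 6.65 times those of counting within Alb-WT, 5.27 to 6.93 times within Alb-Cre replicates 1 to 3 and 34.0 to 36.7 times between these and replicate 4. This rules out only repeated sequencing of the same library. Separate preparations of a shared RNA would exceed counting noise too, so the 8 libraries were counted as samples by their labels.

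Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using empirical Bayes with an intensity trend and the genotype as the only term, over the 11077 rows with a mean of at least 0.5 FPKM. Fold changes are on that log2 scale, which understates changes of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the 38 of 44 lists with at least 5 tested members. Member counts given with the results refer to tested genes only. Tested were 10 of 20 listed T cell genes and 5 of 18 of NK and cytotoxic lymphocytes. For regulatory T cells and checkpoints 2 of 14 were tested, and for female-biased liver genes 4 of 16. The lists, tests and alternatives were fixed before the data were examined, except where a choice is said to have been made after seeing the data. Single values were tested by an exact two-sided permutation over 70 assignments, for which the smallest p is 0.0286. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

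The rule for named genes took Bicd2, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 FPKM and no overlap between groups, and members of each list. Unnamed gene models, immunoglobulin and T cell receptor segments and pseudogenes were left out of the largest changes. Of a list called by camera the 4 members with the smallest p in its direction were named, and of any other list the member with the smallest p where it passed. This gave 105 genes.

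The fit was tested on simulated data for the comparison of Alb-Cre with Alb-WT over 11055 genes. It called 38.8% of genes changed 1.5-fold in the right direction, 95.5% of those changed 2-fold and 100% of those changed 4-fold, with 22 false calls among 10855 unchanged genes. These shares need not hold for genes in which Alb-Cre replicate 4 departed from its group. Cxcl9, picked after its value was seen, had a log2 fold change of -2.55 and was not called (limma adjusted p = 0.058). Its level was 72.8 FPKM in Alb-Cre replicate 4 and 2.12 to 2.96 FPKM in the other Alb-Cre libraries. A shifted list had a camera adjusted p of 1.13e-21, and 0 of 38 random lists were called. Random lists need not carry the correlation between genes of the real lists, estimated at -0.046 (circadian clock) to 0.986 (MHC class II presentation). They therefore cannot show how often camera with its small fixed correlation calls such lists falsely. Regrouping the real libraries across genotypes, as described below, gave 8 to 23 called lists with 0 genes called. The camera p-values of lists may thus be too small. Alternatives were another pseudocount, other filters, other scalings, no trend, robust fitting, array weights, a replicate block, leaving out each library, fold thresholds, and other list tests. Added after seeing the data were voom on the recovered fragments and a correction for gene length, in which the trend of each library's deviations over log2 length was removed by lowess.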

Results

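RNA sequencing was compared between livers of mice carrying loxP-flanked Bicd2 with and without an albumin-driven Cre recombinase, which acts in hepatocytes. Bicd2 encodes an adaptor that links dynein to its cargo. All mice belonged to an autoimmune hepatitis model, in which S-100, a liver antigen preparation, was injected in complete Freund's adjuvant at 2.5 mg weekly for 3 weeks, and livers were taken 2 weeks after the last injection. There were 4 Alb-Cre and 4 Alb-WT libraries. Fragments recovered for the listed genes ranged from 27165623 to 32436571 per library. No untreated liver was analysed here, so values describe the genotype difference within the model. Nothing in the labels says that the libraries came from separate animals, and p-values therefore measure the spread between these samples, which may be technical.

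Bicd2 itself was lower in every Alb-Cre library than in every Alb-WT library. Its level was 0.705, 0.568, 0.509 and 0.732 FPKM in the Alb-Cre libraries and 2.46, 3.02, 2.8 and 3.11 FPKM in the Alb-WT libraries. The means were 0.628 ± 0.107 and 2.85 ± 0.288 FPKM (SD, n = 4 each), a 4.53-fold difference on the FPKM scale that exceeded the spread between replicates (limma log2 fold change -1.24, SE 0.082, adjusted p = 7.25e-05). A two-sided exact permutation test of the group labels gave p = 0.0286, the smallest that 70 assignments allow.

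Lists of lipid synthesis, endoplasmic reticulum chaperone and nuclear-encoded oxidative phosphorylation genes were called higher in Alb-Cre livers, and those of macrophages, neutrophils, interferon responses and antigen presentation lower, by camera with a small fixed correlation between genes. With an estimated correlation none of these calls held, and in Alb-Cre replicate 4 MHC class II genes were not lower than in Alb-WT (score 0.13). Of 11077 genes tested, 939 rose and 2582 fell (limma, adjusted p under 0.05), and 67 and 231 of these changed at least 2-fold on the log2(FPKM + 1) scale. The 4 and 4 values did not overlap for 3393 genes, or 30.6% of those tested, against 2.9% by chance. The median gene had a log2 fold change of -0.13, and the share of lower genes among the calls, 73.3%, depended on scaling: it was 82.9% after rescaling to a common FPKM sum (median gene -0.23), 58.6% with median-of-ratios scaling (median gene -0.05), 48.6% with quantile normalization (median gene 0.02) and 51.8% after a gene length correction chosen after seeing the data (median gene -0.01). With a mean of at least 5 FPKM required, the share was 55.7%.

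Alb-Cre replicate 4 stood apart from the other Alb-Cre libraries. Its Pearson correlation with them, across genes on the log2 scale, was 0.966 to 0.968, whereas replicates 1 to 3 correlated at 0.995 to 0.997 with each other, and the Alb-WT libraries did so at 0.996 to 0.997. With the Alb-WT libraries replicate 4 correlated at 0.980 to 0.982, better than with its own group. Genes are not independent replicates in these values. Without Alb-Cre replicate 4, 1679 genes were higher and 5112 lower, among them all 939 and 2582 above. Leaving out any other library lowered the counts, to 569 higher and 1233 lower without Alb-Cre replicate 1, 753 and 1418 without replicate 2, and 577 and 1263 without replicate 3. The counts were 559 and 1220 without Alb-WT replicate 1, 623 and 1423 without replicate 2, 546 and 1205 without replicate 3, and 672 and 1527 without replicate 4.

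**Figure D1:**
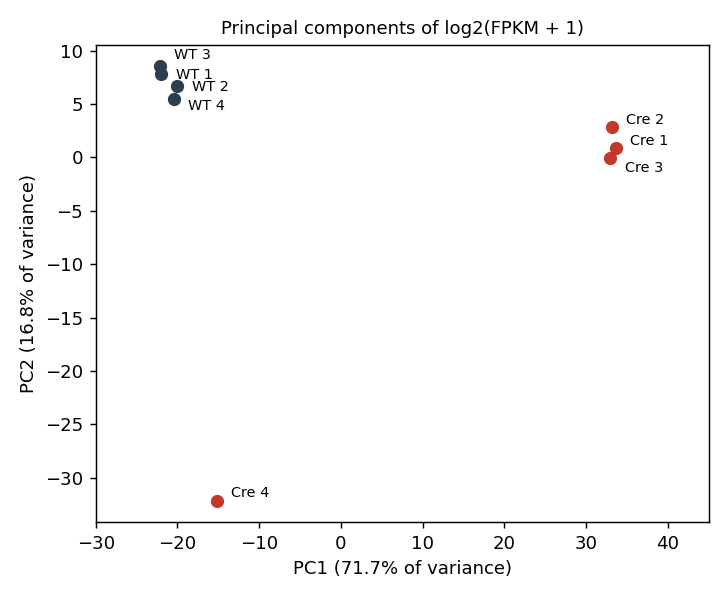
Principal components 1 and 2 of log2(FPKM + 1) for the 4 Alb-WT (dark) and 4 Alb-Cre (red) libraries, each point a library labelled with its replicate number; the axes carry 71.7% and 16.8% of the variance. Alb-Cre replicate 4 lies at -15.2 on component 1 and -32.1 on component 2, apart from both clusters.

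The largest rises among genes without overlap between groups included Apoa4, an apolipoprotein of triglyceride-rich particles, at 118 ± 14 FPKM in Alb-Cre against 19 ± 1.62 in Alb-WT (SD, n = 4, log2 fold change 2.57, SE 0.097, adjusted p = 7.94e-06). Thrsp, a regulator of lipogenesis, reached 137 ± 63.6 FPKM in Alb-Cre against 15.4 ± 0.33 in Alb-WT, with 41.5 FPKM in Alb-Cre replicate 4. Derl3, which takes part in degradation of misfolded proteins of the endoplasmic reticulum, rose to 7.99 ± 3.08 from 1.18 ± 0.152 FPKM. The peroxisomal hydrolase gene Nudt7 rose to 108 ± 43.9 from 24.1 ± 0.608 FPKM. Ugt2b37 (3.55), Nat8f5 (1.96), Gsta1 (2.38) and Cyp4a14 (2.27, log2 fold changes) also rose, as did Mup9 (3.22) and 1 of the 4 rows named Mup13 (2.86). These last 6 belong to families with near-identical members, between which shared reads make the gene-level values uncertain. Alb-Cre replicate 4 had 29.9 FPKM of Gsta1 and 43.5 FPKM of Cyp4a14, against 3.1 to 4.87 and 7.35 to 7.83 FPKM in the others. For Nat8f5 it had 3.68 FPKM, against 3.54 FPKM in Alb-WT replicate 1 and 19.2 to 22.6 FPKM in the other Alb-Cre libraries. It had 43.1 FPKM of Nudt7 and 3.56 FPKM of Derl3, against 124 to 134 and 8.35 to 10.6 FPKM in the others. Without it the log2 fold changes were 1.72 for Gsta1 and 1.68 for Cyp4a14, but 4.21 for Ugt2b37, 3.91 for Mup9 and 3.56 for the Mup13 row.

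The largest falls among genes without overlap between groups were those of S100a9 and S100a8, calcium-binding proteins abundant in neutrophils. S100a9 was 16 ± 22.4 FPKM in Alb-Cre against 179.6 ± 16 in Alb-WT (SD, n = 4, log2 fold change -4.18, SE 0.65, adjusted p = 0.00321), and S100a8 was 8.21 ± 13.3 FPKM in Alb-Cre against 84.7 ± 17.4 in Alb-WT (log2 fold change -4.17, SE 0.73, adjusted p = 0.0055). Next among such genes came Tgtp1 (-3.95), Chil3 (-3.72), Elane (-2.98), the platelet chemokine gene Ppbp (-2.90), Gbp2b (-2.76), Igtp (-2.75), Serpina3f (-2.60) and Gbp2 (-2.49, log2 fold changes). Some called genes with overlap between groups, such as H2-Ab1 (-3.32), fell more than Elane. Tgtp1, Gbp2b, Igtp and Gbp2 encode interferon-inducible GTPases. Alb-Cre replicate 4 lay nearer to the Alb-WT level for these 10 genes, with 28.1 FPKM of S100a8 and 27.1 FPKM of Gbp2. Without it the log2 fold changes were -5.045 for S100a8, -4.959 for S100a9, -4.627 for Tgtp1, -4.435 for Chil3, -3.467 for Gbp2b, -3.255 for Gbp2 and -3.206 for Serpina3f. The call for Gbp2 was lost on leaving out any of 6 single libraries, and that for Nat8f5 without Alb-Cre replicate 1 (adjusted p = 0.0517) or 3 (0.0525) and with voom (0.0523).

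**Figure D2:**
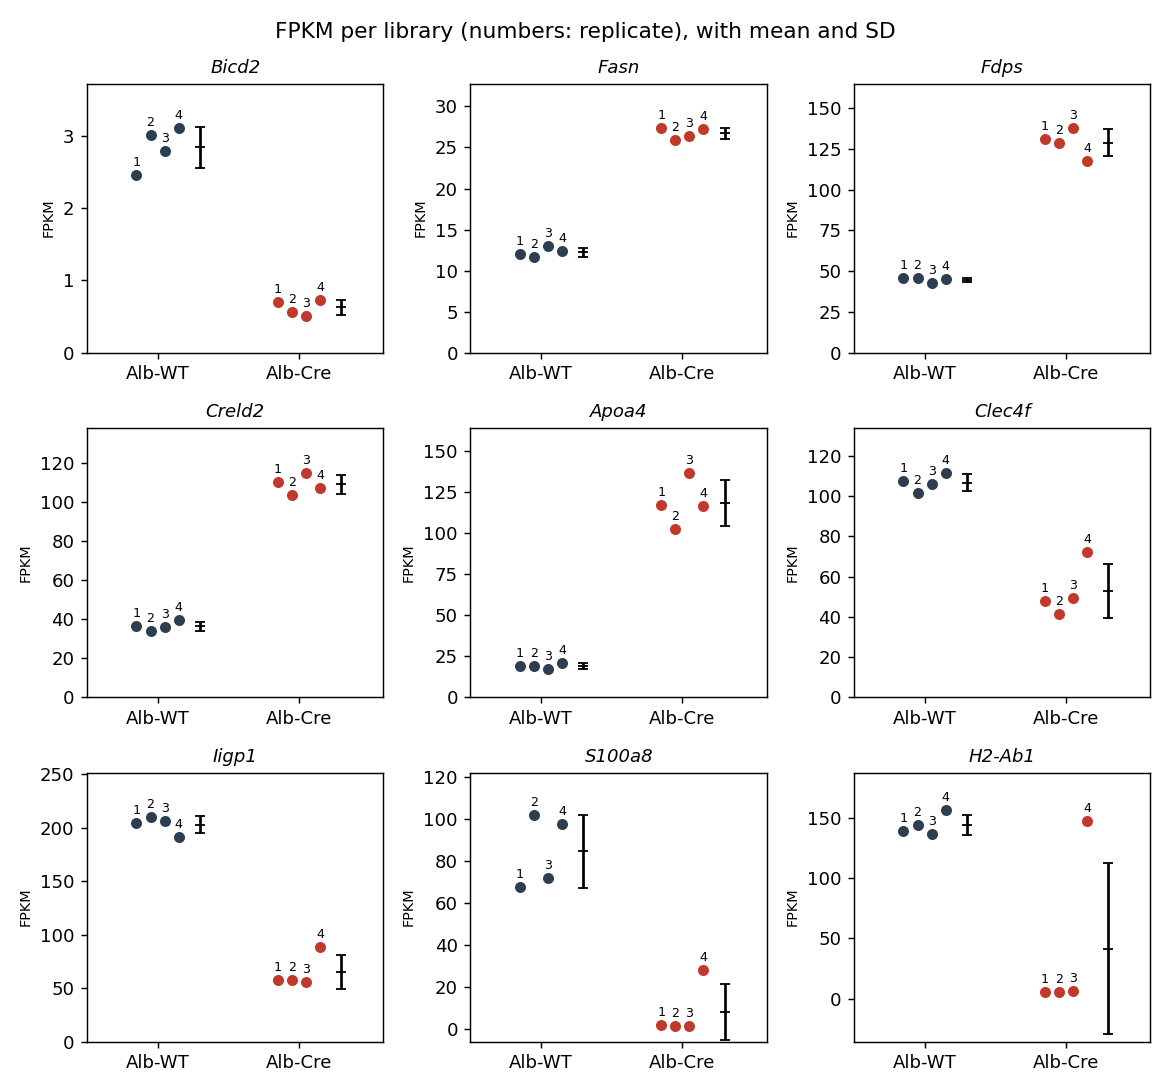
FPKM of 9 genes in each library, with Alb-WT in dark and Alb-Cre in red, replicate numbers above the points, and the mean with its SD beside each group of 4. All of these genes but H2-Ab1 separate the groups in all libraries, whereas H2-Ab1 reaches 148 FPKM in Alb-Cre replicate 4 and 5.28 to 6.06 FPKM in the other Alb-Cre libraries.

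Genes of cholesterol synthesis were higher in Alb-Cre livers. Of 22 tested members 14 rose, none fell and 8 did not pass (15 rose when adjusted over the list alone). Fdps, which makes farnesyl diphosphate, was 129 ± 8.31 FPKM in Alb-Cre against 44.7 ± 1.39 in Alb-WT (SD, n = 4, log2 fold change 1.5, SE 0.066, adjusted p = 9.42e-06). Nsdhl, Dhcr7 and Pmvk, further enzymes of the pathway, rose by 0.89, 0.88 and 1.16 on the log2 scale. The mean log2 fold change of the list was 0.49 (camera adjusted p = 1.6e-10, and adjusted p = 0.302 with an estimated correlation). List scores, which are mean log2(FPKM + 1) values less the Alb-WT mean, were 0.41, 0.35 and 0.42 in Alb-Cre replicates 1 to 3 and 0.79 in replicate 4.

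Fatty acid and triglyceride synthesis genes rose as well, 10 of 21, with none lower and 11 not passing (12 adjusted over the list alone). Fasn, the fatty acid synthase, was 26.7 ± 0.672 FPKM in Alb-Cre against 12.3 ± 0.549 in Alb-WT (SD, n = 4, log2 fold change 1.06, SE 0.057, adjusted p = 3.01e-05). Scd1, a desaturase, was 1001 ± 25.2 FPKM in Alb-Cre against 528 ± 13.4 in Alb-WT, and the pyruvate kinase gene Pklr 31.5 ± 2.58 FPKM in Alb-Cre against 14.2 ± 1.41 in Alb-WT. Acacb, an acetyl-CoA carboxylase, rose by 1.61 on the log2 scale, with 6.83 FPKM in Alb-Cre replicate 4 against 13.9 to 14 FPKM in the others. Acaca, another acetyl-CoA carboxylase gene, and the regulator gene Srebf1, both picked after their values were seen, were not called. Their log2 fold changes were 0.18 and 0.01 (limma adjusted p = 0.295 and 0.917). The list's mean log2 fold change was 0.62 (camera adjusted p = 2.42e-09, and adjusted p = 0.302 with an estimated correlation). Its scores were 0.72, 0.71 and 0.71 in Alb-Cre replicates 1 to 3 and 0.33 in replicate 4.

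Chaperones and folding factors of the unfolded protein response were higher. In this list 12 of 22 genes rose, 1 fell (Asns, an amino acid synthesis enzyme, named here after its value was seen) and 9 did not pass. Adjusted over the list alone, 13 rose and 4 fell. Besides Asns, those that fell were Atf3 (-0.83) and the stress sensor genes Atf6 (-0.25) and Ern1 (-0.30, log2 fold changes). Ddit3 (-0.04), Atf4 (0.19), Chac1 (-0.39) and Trib3 (0.27) passed in neither adjustment. These genes too were named after their values were seen. Creld2 was 109 ± 4.74 FPKM in Alb-Cre against 36.5 ± 2.32 in Alb-WT (SD, n = 4, log2 fold change 1.56, SE 0.067, adjusted p = 9.42e-06). Sdf2l1, Manf and Pdia6 rose by 1.44, 1.12 and 0.97 on the log2 scale. The mean over the list was 0.35 (camera adjusted p = 2.29e-09, and adjusted p = 0.302 with an estimated correlation), with scores of 0.26, 0.25 and 0.27 in Alb-Cre replicates 1 to 3 and 0.61 in replicate 4. Among 26 genes of ER-Golgi trafficking 9 rose, 3 fell and 14 did not pass (14 and 3 adjusted over the list alone). Cope, a coatomer subunit, rose by 0.64, and the cargo receptor and transport genes Tmed2, Arf4 and Lman1 by 0.43, 0.44 and 0.28 on the log2 scale. The call for Arf4 was lost without Alb-WT replicate 1 (adjusted p = 0.0524) or 4 (0.0509), and that for Lman1 without Alb-WT replicate 3 (0.0522). Both were also lost after rescaling to a common FPKM sum (0.0649 and 0.113) and with the replicate block (0.0549 and 0.0545), and that for Tmed2 with quantile normalization (0.0621). Golgb1, Mia2 and Mia3, the members that fell and were named after their values were seen, encode a golgin and secretory cargo factors. The mean of this list was 0.18 (camera adjusted p = 2.31e-05, and adjusted p = 0.668 with an estimated correlation and 0.161 by fry), and the scores were 0.10, 0.10 and 0.12 in Alb-Cre replicates 1 to 3 and 0.41 in replicate 4.

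Nuclear-encoded subunits of oxidative phosphorylation rose in 13 of 23 cases, with none lower and 10 not passing (15 adjusted over the list alone). Atp5g1 was 42.6 ± 2.42 FPKM in Alb-Cre against 30.5 ± 2.18 in Alb-WT (SD, n = 4, log2 fold change 0.47, SE 0.072, adjusted p = 0.00307), and Cox7a2, Sdhb and Ndufb3 rose by 0.53, 0.30 and 0.66 on the log2 scale, the call for Sdhb being lost with quantile normalization (adjusted p = 0.0979). The list mean was 0.30 (camera adjusted p = 3.3e-11, and adjusted p = 0.302 with an estimated correlation), with scores of 0.35, 0.21 and 0.40 in Alb-Cre replicates 1 to 3 and 0.24 in replicate 4, and -0.04, 0.04, -0.07 and 0.07 in Alb-WT replicates 1 to 4. Within each genotype these scores nearly followed the gene length trend of the libraries (Spearman's rho with length -0.23, -0.18, -0.26 and -0.18 in Alb-Cre replicates 1 to 4, and 0.15, -0.11, 0.21 and -0.25 in Alb-WT). After the gene length correction, chosen after seeing the data, the list mean was 0.32 (camera adjusted p = 1.6e-07), with scores of 0.38, 0.31, 0.42 and 0.17 in Alb-Cre and -0.06 to 0.05 in Alb-WT. Among PPAR-alpha and fatty acid oxidation genes 9 of 24 rose, 2 fell and 13 did not pass (10 and 3 adjusted over the list alone). Cyp4a10 (1.79) and Cyp4a14 (2.27), fatty acid hydroxylases, the lipid droplet gene Plin2 (0.59) and the dehydrogenase gene Acadl (0.31, call lost with quantile normalization, adjusted p = 0.0712) rose on the log2 scale. Ppara (-0.39) and Ppargc1a (-0.70), which encode the list's own regulators and were named after their values were seen, fell. This list had a mean of 0.31 (camera adjusted p = 0.000209, and adjusted p = 0.604 with an estimated correlation and 0.164 by fry). It was not called with quantile normalization (adjusted p = 0.067), and had scores of 0.39, 0.37 and 0.39 in Alb-Cre replicates 1 to 3 and 0.10 in replicate 4.

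Genes with male-biased expression in liver rose in 5 of 15 cases, with 10 not passing (5 adjusted over the list alone). Selenbp2 was 354 ± 146 FPKM in Alb-Cre against 93.3 ± 5.68 in Alb-WT (SD, n = 4, log2 fold change 1.77, SE 0.34, adjusted p = 0.00789), with 136 FPKM in Alb-Cre replicate 4. Nudt7, Cyp4a12b and Ugt2b38 rose by 2.00, 0.90 and 1.86 on the log2 scale, and the call for Ugt2b38 was lost on leaving out any of 7 single libraries and with voom (adjusted p = 0.0654). The list mean was 0.88 (camera adjusted p = 0.000299, and adjusted p = 0.714 with an estimated correlation and 0.359 by fry); quantile normalization gave adjusted p = 0.091. Its scores were 1.36, 1.42 and 1.36 in Alb-Cre replicates 1 to 3 and -0.63 in replicate 4, so that replicate 4 lay below every Alb-WT library, and an exact permutation test of the score gave p = 0.143.

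**Figure D3:**
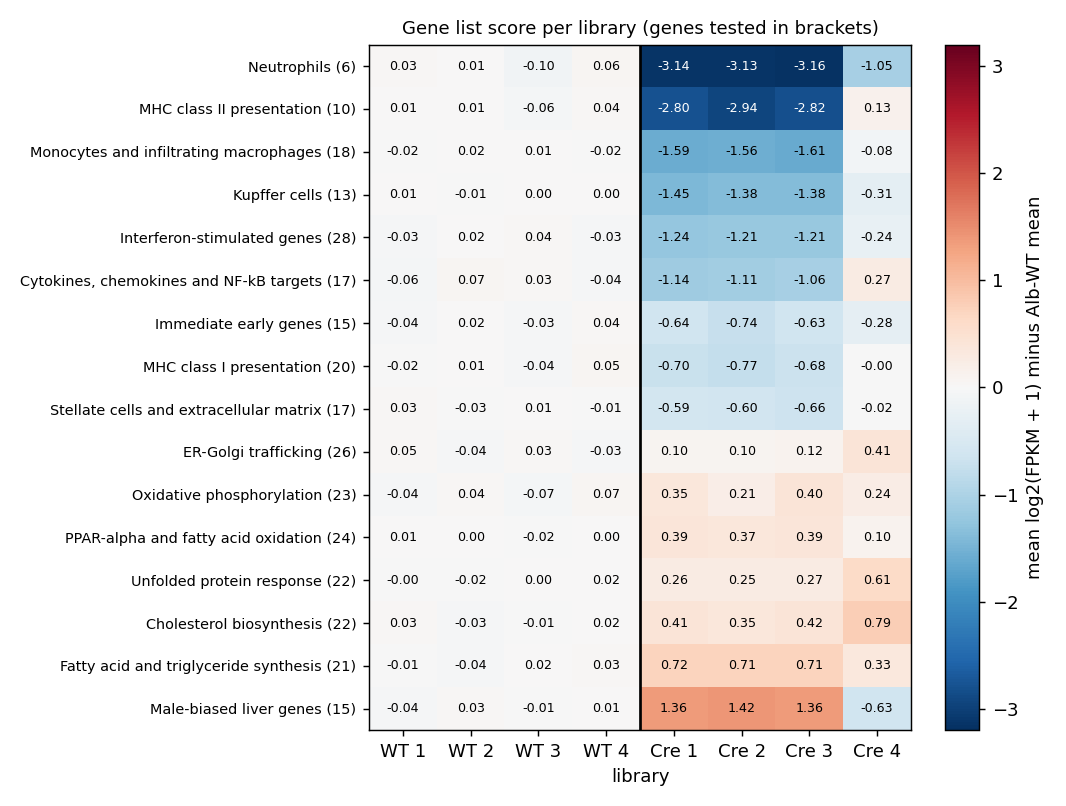
Scores of the 16 gene lists called by camera in each library, as mean log2(FPKM + 1) over the list less the mean of the Alb-WT libraries, with the number of genes tested in brackets; red is higher and blue lower. Alb-Cre replicate 4 lies near the Alb-WT libraries for MHC class II presentation (0.13) and below them for male-biased genes (-0.63).

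Macrophage and neutrophil genes were lower in Alb-Cre livers. All 13 tested genes of Kupffer cells, the resident liver macrophages, fell (also 13 adjusted over the list alone). Clec4f, a Kupffer cell lectin, was 52.8 ± 13.4 FPKM in Alb-Cre against 107 ± 4.17 in Alb-WT (SD, n = 4, log2 fold change -1.03, SE 0.15, adjusted p = 0.00237), and Slc40a1, Vsig4 and Folr2 fell by 0.88, 1.06 and 0.67 on the log2 scale. The mean of the list was -1.13 (camera adjusted p = 8.89e-05, and adjusted p = 0.604 with an estimated correlation), and scores were -1.45, -1.38 and -1.38 in Alb-Cre replicates 1 to 3 and -0.31 in replicate 4. Of 18 genes of monocytes and infiltrating macrophages 11 fell, none rose and 7 did not pass (15 adjusted over the list alone). Ly6c2 was 0.731 ± 0.871 FPKM in Alb-Cre against 5 ± 0.613 in Alb-WT (log2 fold change -1.90, SE 0.27, adjusted p = 0.00225). Chil3, Adgre1 and the chemokine receptor gene Ccr2 fell by 3.72, 1.59 and 1.40. In liver RNA the fall of Adgre1, a macrophage gene, cannot be assigned to infiltrating cells rather than Kupffer cells, whose genes fell too. The mean of the monocyte list was -1.21 (camera adjusted p = 0.000963, and adjusted p = 0.714 with an estimated correlation), with scores of -1.59, -1.56 and -1.61 in Alb-Cre replicates 1 to 3 and -0.08 in replicate 4. Neutrophil genes fell in all 6 tested cases, and in 6 adjusted over the list alone. This list held 16 genes, of which 8 were in the deposited data and 6 passed the expression filter. Elane, the neutrophil elastase, was 0.837 ± 1.31 FPKM in Alb-Cre against 11.6 ± 1.81 in Alb-WT (log2 fold change -2.98, SE 0.36, adjusted p = 0.00106), and Mmp9 was 0.306 ± 0.151 FPKM in Alb-Cre against 1.34 ± 0.264 in Alb-WT. S100a8 and S100a9, given above, are the others of the 4 named. The neutrophil mean was -2.62 (camera adjusted p = 0.00216, and adjusted p = 0.604 with an estimated correlation), and the scores were -3.14, -3.13 and -3.16 in Alb-Cre replicates 1 to 3 and -1.05 in replicate 4.

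Interferon-stimulated genes fell in 20 of 28 cases, with none higher and 8 not passing (24 adjusted over the list alone). Iigp1, an interferon-inducible GTPase, was 64.8 ± 15.8 FPKM in Alb-Cre against 203 ± 7.95 in Alb-WT (SD, n = 4, log2 fold change -1.66, SE 0.14, adjusted p = 0.000228), and Irgm1 was 11.5 ± 3.15 FPKM in Alb-Cre against 28.8 ± 0.452 in Alb-WT. Ifit3 and Rsad2, antiviral effectors, fell by 0.80 and 0.60 on the log2 scale. The list mean was -0.97 (camera adjusted p = 4.5e-06, and adjusted p = 0.607 with an estimated correlation), with scores of -1.24, -1.21 and -1.21 in Alb-Cre replicates 1 to 3 and -0.24 in replicate 4. In the list of cytokines, chemokines and NF-kB targets 5 of 17 fell and 12 did not pass (9 adjusted over the list alone). Il1b was 2.39 ± 0.737 FPKM in Alb-Cre against 5.09 ± 0.617 in Alb-WT (log2 fold change -0.86, SE 0.15, adjusted p = 0.00466), and Nfkbia, Tnfaip3 and Il1a fell by 0.68, 0.99 and 0.54, the call for Il1a being lost on leaving out any of 6 single libraries, with quantile normalization (adjusted p = 0.093) and with the replicate block (0.0811). The mean was -0.76 (camera adjusted p = 0.0147, and adjusted p = 0.714 with an estimated correlation and 0.0855 by fry), and scores were -1.14, -1.11 and -1.06 in Alb-Cre replicates 1 to 3 and 0.27 in replicate 4, replicate 4 being above the Alb-WT libraries (exact permutation p = 0.143 for the score). Immediate early genes fell in 8 of 15 cases, with 7 not passing (10 adjusted over the list alone). Zfp36 was 26.3 ± 1.77 FPKM in Alb-Cre against 44.4 ± 1.51 in Alb-WT (log2 fold change -0.74, SE 0.065, adjusted p = 0.000255), while Nr4a1, Dusp1 and Fosl2 fell by 1.20, 1.05 and 0.68. Their mean was -0.57 (camera adjusted p = 0.0116, and adjusted p = 0.514 with an estimated correlation), with adjusted p = 0.0959 when a mean of at least 5 FPKM was required, and scores were -0.64, -0.74 and -0.63 in Alb-Cre replicates 1 to 3 and -0.28 in replicate 4.

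Antigen presentation genes were lower, with a wide spread among the Alb-Cre libraries. Of 10 genes of MHC class II presentation 8 fell and 2 did not pass (9 adjusted over the list alone). H2-Ab1 was 41.1 ± 70.9 FPKM in Alb-Cre against 144 ± 8.68 in Alb-WT (SD, n = 4, log2 fold change -3.32, SE 0.92, adjusted p = 0.0272), and H2-Aa was 33.3 ± 56.1 FPKM in Alb-Cre against 106 ± 3.26 in Alb-WT. Alb-Cre replicate 4 had 148 and 117 FPKM of them, within or above the Alb-WT values, and the calls for H2-Ab1, H2-Aa and H2-DMb1 were lost on leaving out any of the 7 other libraries. Without replicate 4 the log2 fold changes of these 3 genes were -4.44, -4.10 and -2.97. Ciita, the transactivator of class II genes, fell by 1.18 on the log2 scale and H2-DMb1 fell by 2.25. The class II mean was -2.11 (camera adjusted p = 0.0149, and adjusted p = 0.714 with an estimated correlation and 0.0611 by fry), with scores of -2.80, -2.94 and -2.82 in Alb-Cre replicates 1 to 3 and 0.13 in replicate 4 and an exact permutation p = 0.143. For MHC class I presentation 14 of 20 genes fell, 2 rose (Calr and Pdia3, chaperones of the endoplasmic reticulum, named after their values were seen) and 4 did not pass (15 and 2 adjusted over the list alone). Erap1 was 9.44 ± 0.542 FPKM in Alb-Cre against 15.7 ± 0.658 in Alb-WT (log2 fold change -0.67, SE 0.063, adjusted p = 0.000313), and the peptide transporter gene Tap1, H2-Q4 and Nlrc5 fell by 1.36, 1.14 and 0.98. The class I mean was -0.54 (camera adjusted p = 0.034, and adjusted p = 0.714 with an estimated correlation and 0.0761 by fry), with scores of -0.70, -0.77 and -0.68 in Alb-Cre replicates 1 to 3 and 0.00 in replicate 4 and an exact permutation p = 0.0857. This call was lost without Alb-Cre replicate 2 (adjusted p = 0.0549), Alb-WT replicate 2 (0.0503) or Alb-WT replicate 4 (0.0613), and after rescaling to a common FPKM sum (0.0697).

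Stellate cell and extracellular matrix genes fell in 8 of 17 cases; 1 rose (Acta2, a smooth muscle actin, named after its value was seen) and 8 did not pass (10 and 1 adjusted over the list alone). Dcn, a matrix proteoglycan, was 23.5 ± 0.753 FPKM in Alb-Cre against 37 ± 1.23 in Alb-WT (SD, n = 4, log2 fold change -0.64, SE 0.056, adjusted p = 0.000255). Thbs1, Postn and the collagen gene Col1a2 fell by 0.98, 0.57 and 0.85 on the log2 scale, with 3.09 FPKM of Col1a2 in Alb-Cre replicate 4 and its call lost on leaving out any of 6 single libraries. The mean was -0.47 (camera adjusted p = 0.02, and adjusted p = 0.714 with an estimated correlation), rescaling to a common FPKM sum gave adjusted p = 0.0561, and scores were -0.59, -0.60 and -0.66 in Alb-Cre replicates 1 to 3 and -0.02 in replicate 4 (exact permutation p = 0.0571).

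The other lists were not called by camera. Among T cell genes 0 of 10 genes rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.183). Its score was 0.27 in Alb-Cre replicate 4 and -0.82, -0.80 and -0.80 in replicates 1 to 3. Icos was 0.305 ± 0.41 FPKM in Alb-Cre against 1.25 ± 0.169 in Alb-WT (SD, n = 4). For NK and cytotoxic lymphocytes 0 of 5 genes rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.204). Its score was 0.39 in Alb-Cre replicate 4 and -1.50, -1.70 and -1.59 in replicates 1 to 3. Klrk1 fell by 0.60 on the log2 scale. In the list of B and plasma cells, whose mean (0.16) and median (-0.20) differed in sign, 1 of 7 genes rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.308). Its score was 1.15 in Alb-Cre replicate 4 and -0.16, -0.19 and -0.17 in replicates 1 to 3. Derl3 was the member that rose. Of 2 regulatory T cell and checkpoint genes, too few for camera, Cd274 fell by 1.77 (2.36 without Alb-Cre replicate 4, and call lost on leaving out any of 7 single libraries, with 6 FPKM in Alb-Cre replicate 4), and 1 rose and 1 fell adjusted over the list alone. Of 4 dendritic cell genes 1 fell (3 adjusted over the list alone), Irf8 by 1.26 with 4.7 FPKM in replicate 4 and the call lost on leaving out any of 6 single libraries. For sinusoidal and vascular endothelium 0 of 13 genes rose and 4 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.3). Its score was -0.38 in Alb-Cre replicate 4 and -0.14, -0.15 and -0.13 in replicates 1 to 3. Lyve1 was 2.58 ± 0.207 FPKM in Alb-Cre against 5.29 ± 0.394 in Alb-WT. Among cholangiocyte and ductular genes 0 of 8 genes rose and 5 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.204). Its score was -0.03 in Alb-Cre replicate 4 and -0.54, -0.52 and -0.52 in replicates 1 to 3. Cd24a fell by 1.47. For erythroid cells and blood 0 of 6 genes rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.213). Its score was -1.48 in Alb-Cre replicate 4 and -0.68, -0.57 and -0.63 in replicates 1 to 3. Hbb-bt was 16.5 ± 4.78 FPKM in Alb-Cre against 83.3 ± 11.8 in Alb-WT. Of fat and mesothelium genes 1 of 5 genes rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.0989). Its score was -0.38 in Alb-Cre replicate 4 and -0.85, -0.82 and -0.78 in replicates 1 to 3. Msln fell by 1.69. Of 2 pancreas genes 1 rose, Cela1, by 1.74, also 1 adjusted over the list alone, with 4.39 FPKM in replicate 4.

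None of the hepatocyte, metabolic and clock lists in this paragraph was called by camera. For hepatocyte identity, with median -0.15 and mean -0.03 but a camera direction upward, 3 of 17 genes rose and 2 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.9). Its score was -0.37 in Alb-Cre replicate 4 and 0.08, 0.07 and 0.12 in replicates 1 to 3. Tat was 956 ± 38.5 FPKM in Alb-Cre against 1315 ± 45.1 in Alb-WT (SD, n = 4). Among pericentral genes 2 of 15 genes rose and 5 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.7). Its score was -0.08 in Alb-Cre replicate 4 and -0.28, -0.26 and -0.19 in replicates 1 to 3. Slc1a2 fell by 1.05 on the log2 scale. Among periportal genes 0 of 17 genes rose and 5 fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.308). Its score was -0.62 in Alb-Cre replicate 4 and -0.17, -0.19 and -0.13 in replicates 1 to 3. Pck1, a gluconeogenic enzyme, was 873 ± 64.1 FPKM in Alb-Cre against 1540 ± 45.3 in Alb-WT. In gluconeogenesis and glycolysis, with mean -0.13, median 0.07 and camera direction upward, 5 of 18 genes rose and 5 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.0806). Its score was 0.00 in Alb-Cre replicate 4 and -0.17, -0.19 and -0.17 in replicates 1 to 3. Irs2 fell by 1.30. For bile acid synthesis and transport 1 of 18 genes rose and 9 fell (1 and 10 adjusted over the list alone, camera adjusted p = 0.0684). Its score was -0.76 in Alb-Cre replicate 4 and -0.33, -0.30 and -0.32 in replicates 1 to 3. Slco1a4 fell by 0.95, and the list passed without Alb-Cre replicate 1 (adjusted p = 0.0323), 2 (0.0229) or 3 (0.0299), with a mean of at least 5 FPKM (0.0097), with quantile normalization (0.000463), after the gene length correction (0.0161) and by fry (0.0189). Among xenobiotic metabolism genes, camera direction upward against a mean of -0.08 and median of -0.07, 5 of 20 genes rose and 6 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.419). Its score was -0.35 in Alb-Cre replicate 4 and -0.02, 0.06 and 0.00 in replicates 1 to 3. Ces2c, a carboxylesterase, was 14.8 ± 0.318 FPKM in Alb-Cre against 3.82 ± 0.353 in Alb-WT. In the circadian clock list 4 of 15 genes rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.185). Its score was 0.07 in Alb-Cre replicate 4 and 0.00, -0.03 and 0.04 in replicates 1 to 3. Cry1 was 2.78 ± 0.402 FPKM in Alb-Cre against 5.74 ± 0.425 in Alb-WT.

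Stress and housekeeping lists were not called by camera either. In the acute phase response, mean -0.14 and median -0.09 with camera direction upward, 3 of 22 genes rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.204). Its score was 1.04 in Alb-Cre replicate 4 and -0.53, -0.58 and -0.51 in replicates 1 to 3. Saa4 rose by 0.28 on the log2 scale, a call lost on leaving out any of 4 single libraries, after rescaling to a common FPKM sum (adjusted p = 0.112), with quantile normalization (0.162) and with the replicate block (0.0617). For innate nucleic acid and pattern sensing 0 of 16 genes rose and 4 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.204). Its score was 0.06 in Alb-Cre replicate 4 and -0.59, -0.51 and -0.60 in replicates 1 to 3. Tlr4 fell by 0.66. Among cell death effectors 0 of 21 genes rose and 7 fell (0 and 8 adjusted over the list alone, camera adjusted p = 0.419). Its score was 0.02 in Alb-Cre replicate 4 and -0.38, -0.46 and -0.42 in replicates 1 to 3. Casp1 fell by 1.26. Of ferroptosis and NRF2 antioxidant genes, mean 0.11 and median -0.07, 3 of 19 genes rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.313). Its score was 0.43 in Alb-Cre replicate 4 and 0.00, 0.00 and 0.01 in replicates 1 to 3. Gstm3 rose by 1.48. For autophagy and lysosome 1 of 23 genes rose and 7 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.389). Its score was -0.12 in Alb-Cre replicate 4 and -0.20, -0.21 and -0.16 in replicates 1 to 3. Ctsb was 112 ± 13.4 FPKM in Alb-Cre against 165 ± 3.33 in Alb-WT (SD, n = 4). Of proliferation genes 0 of 15 genes rose and 6 fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.596). Its score was 0.12 in Alb-Cre replicate 4 and -0.44, -0.35 and -0.34 in replicates 1 to 3. Ccna2 fell by 0.64. For p53 targets and senescence 1 of 14 genes rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.529). Its score was -0.11 in Alb-Cre replicate 4 and -0.33, -0.35 and -0.34 in replicates 1 to 3. Trp53inp1 was 16.1 ± 1.9 FPKM in Alb-Cre against 39 ± 2.13 in Alb-WT. In dynein, dynactin and BICD adaptor genes other than Bicd2, mean -0.08 and median -0.11 with camera direction upward, 2 of 21 genes rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.92). Its score was 0.07 in Alb-Cre replicate 4 and -0.12, -0.16 and -0.11 in replicates 1 to 3. Hook3 fell by 0.33, a call lost with quantile normalization (adjusted p = 0.243) and after the gene length correction (0.45). Of 4 female-biased liver genes 1 rose, Cyp2a4, by 0.99, and 1 adjusted over the list alone. Of 4 sex chromosome genes 1 fell, Ddx3y, by 0.44 (call lost after the gene length correction, adjusted p = 0.0536), likewise 1 adjusted over the list alone, and all 4 were Y-linked and present in all 8 libraries. No member of the mitochondrially encoded list was found under its listed symbol.

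Calls by camera assume a small fixed correlation between genes. With the correlation estimated from the data, none of the 38 tested lists passed, and 4 did so at an unadjusted p under 0.05. Fry called 4 lists higher and 15 lower, but not 6 of the 16: ER-Golgi trafficking, PPAR-alpha and fatty acid oxidation, male-biased liver genes, cytokines and NF-kB targets, MHC class II and MHC class I presentation. Without Alb-Cre replicate 4, with the fixed correlation, 4 further lists passed: T cells (adjusted p = 0.00244), NK and cytotoxic lymphocytes (0.0206) and innate nucleic acid and pattern sensing (0.0303) as lower, and xenobiotic metabolism (0.0287, mean log2 fold change 0.01) as higher relative to other genes.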

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

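The tests of explanations below were chosen after the results were seen, as were the gene sets behind the feeding and clock tests. Within each group of 4, a library was singled out where its gap to the nearest other, as a share of the group's whole range, exceeded Dixon's 95% critical value for 4 samples. Over 286 groups of 105 named genes and 38 lists, 76 passed, against about 14 by chance, as chance gives about 1 in 20. The 286 groups are not independent, as all use the same 8 libraries and lists share genes with the named ones. Most named genes were also picked by their values here, so the 14 is only a guide. Of the 76, 71 were Alb-Cre replicate 4, in 41 genes and 30 lists.

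Alb-Cre replicate 4 was the highest of its group for the genes H2-Aa (0.99), Sdf2l1 (0.98), Cyp4a14, S100a8 and Gbp2b (0.97), H2-Ab1 and Irs2 (0.96), S100a9, Cd274 and Adgre1 (0.95), Gbp2 and Vsig4 (0.94), Iigp1 and Ccna2 (0.93), Chil3, Serpina3f and H2-DMb1 (0.92), Elane and Thbs1 (0.91), Irf8, Ciita and Tlr4 (0.90), Igtp (0.89), Tgtp1, Col1a2 and Slc1a2 (0.88), Ccr2, Casp1 and Cyp4a10 (0.87) and Klrk1 (0.86), where the number is the gap share. It was the lowest of its group for Acacb (0.99), Selenbp2 (0.96), Thrsp (0.95), Ugt2b37 and Nudt7 (0.93), Cela1 and Ugt2b38 (0.92), Nat8f5 (0.91), Cyp4a12b (0.87), Plin2 (0.86) and Dusp1 (0.83).

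Among list scores Alb-Cre replicate 4 was highest for neutrophils, T cells and B and plasma cells (0.98), unfolded protein response, interferon-stimulated genes, monocytes and ferroptosis and NRF2 antioxidant genes (0.97), acute phase response and cholangiocytes and ductular reaction (0.96), MHC class II presentation (0.95), Kupffer cells and cytokine and NF-kB genes (0.94), ER-Golgi trafficking (0.93), p53 targets and senescence (0.92), gluconeogenesis and glycolysis (0.91), NK and cytotoxic lymphocytes (0.90), stellate cells and extracellular matrix (0.89), MHC class I presentation (0.88), innate nucleic acid and pattern sensing (0.87), fat and mesothelium (0.85) and cholesterol biosynthesis and cell death effectors (0.84). It was lowest for fatty acid and triglyceride synthesis (0.98), male-biased liver genes (0.97), PPAR-alpha and fatty acid oxidation and bile acid synthesis and transport (0.92), sinusoidal and vascular endothelium (0.91), hepatocyte identity (0.90) and erythroid cells and blood and periportal hepatocyte genes (0.88). Outside that library, Alb-WT replicate 2 was highest for S100a9 (0.88) and lowest for fat and mesothelium (0.87), Alb-WT replicate 3 highest for Tlr4 (0.83), Alb-WT replicate 4 lowest for Slc40a1 (0.89), and Alb-WT replicate 1 highest for xenobiotic metabolism (0.90).

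The first pattern weighed is the distance of Alb-Cre replicate 4 from the other Alb-Cre libraries. A wrong genotype label is argued against by Bicd2, whose level there was 0.3 of that in the lowest Alb-WT library. A larger share of immune cells as the whole cause is argued against by male-biased hepatocyte genes, whose score fell by 1.55 log2 units more than that of hepatocyte identity genes, relative to the other Alb-Cre libraries. A larger share as a part of the cause is not excluded. A difference in disease course or in handling of that liver stays open as a hypothesis that was not tested.

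The second pattern is how close the Alb-WT libraries lie, which holds for Alb-Cre replicates 1 to 3 as well (Pearson correlations of 0.996 to 0.997 and 0.995 to 0.997). Over 6 genes chosen after their values were seen, the coefficient of variation in Alb-WT was 0.94% (Elovl3), 1.95% (Igfbp1), 3.4% (G6pc), 5.61% (Cyp7a1), 8.06% (Saa1) and 14.37% (Mt1). Were these pooled livers or preparations from a shared RNA source, genes that respond to time and handling would vary no more than others. The median SD of 52 clock, immediate early and acute phase genes, 0.084 on the log2 scale against 0.072 in expression-matched lists, lay at percentile 87.3 of 10000 such lists, so a shared source may hold and was not excluded. The same genes had a median SD of 0.073 in Alb-Cre replicates 1 to 3 (percentile 24.3) and of 0.386 with replicate 4 included (percentile 100). Closely matched separate animals stay open too.

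The third pattern is a difference in feeding and clock genes between genotypes. Fed-state less fasted-state genes differed by 1.78 log2 units (10 and 9 genes; 1.53 to 1.95 in Alb-Cre, -0.05 to 0.03 in Alb-WT; exact permutation p = 0.0286, the smallest possible). Genes of the Dbp arm of the clock less those of the Arntl arm differed by 1.11 units (5 and 5 genes; 0.97 to 1.46 against -0.03 to 0.03; exact permutation p = 0.0286). A different feeding state or clock phase at harvest cannot be told apart from an effect of genotype, because the times of feeding and harvest are not given in the sources used here, would be confounded with the groups, and the genes were picked after their values were seen. The genotype stays open as an untested explanation.

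Chance as the source of the gene calls was examined by splitting the 8 libraries into 4 and 4 in all 35 ways. Only the real split, 1 of 35, gave as many as 3521 genes, the smallest share that 35 splits allow. Every other split mixes libraries of both genotypes, which widens the spread within groups and so favours the real split. At that level chance assignment of these libraries is unlikely for the number of genes. Other differences shared by a group are not excluded, nor are chance differences between animals should libraries share a source. The highest other split gave 0 by limma, and other splits up to 3748 at an unadjusted p under 0.05 against 5173 in the real split. Each of the other splits still called at least 8 lists while calling 0 genes. For the 16 lists, 5 of 35 splits gave as many, the highest other giving 23, so that chance cannot be excluded for the number of lists. The 4 other splits set Alb-Cre replicates 1 to 3 with 1 Alb-WT library, giving 21 to 23 lists, which points to a structure of the samples in which Alb-Cre replicate 4 correlates better with Alb-WT (0.980 to 0.982) than with the other Alb-Cre libraries (0.966 to 0.968), though less well than the Alb-WT libraries with each other.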

How the results depend on the processing

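Voom on recovered fragments and the gene length correction were chosen after seeing the data. Bicd2 kept its direction and its side of the threshold in every alternative in which it was tested. Of the 105 named genes, 75 of which had the mean of at least 5 FPKM that the strictest filter asks for, Bicd2 not among them, 87 stayed past the threshold in all alternatives that tested them, 18 lost the call in at least 1, and none changed direction. Without Alb-Cre replicate 4 the fold of 16 of them moved by over 1.5 times. Leaving out Alb-Cre replicate 4 ended no named gene's call, and leaving out each other library ended between 7 and 11. No gene was called in the opposite direction under any alternative. Among list values 759 kept their side, 36 gained a call, 30 lost it and 1 reversed: the hepatocyte identity list was called lower with quantile normalization (-0.12, camera adjusted p = 0.0497, against 0.0497 to 0.967 over its alternatives), and the cause was not tested.

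Genes higher, 939 in the result, numbered 619 after rescaling to a common FPKM sum, 1424 with median-of-ratios scaling, 1400 after the gene length correction, 1554 with quantile normalization and 1772 with array weights, which gave Alb-Cre replicate 4 a weight of 0.078. Genes lower, 2582 in the result, numbered 981 with a mean of at least 5 FPKM, where 4754 genes were tested, 1469 with quantile normalization, 1505 after the gene length correction and 5243 with array weights. Leaving out each library gave 546 to 1679 higher and 1205 to 5112 lower genes. Requiring at least 2-fold besides the adjusted p left 67 higher and 231 lower, by construction fewer. With at least 2-fold and an unadjusted p under 0.05 the counts were 71 and 260. Voom gave 936 and 2863. Apart from the thresholds, the filter and the libraries left out, the cause was not tested.

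With the replicate number as a block, 613 genes were higher and 1631 lower. Same-numbered libraries correlated at -0.065, -0.054, -0.097 and 0.013 in their deviations from the group means. No sample correlated best with its own number, so the numbers showed no pairing of the samples.

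Lists higher, 7 in the result, numbered 0 with an estimated correlation in camera, where 4 lists of either direction had an unadjusted p under 0.05, and 4 with fry. Lists lower, 9 in the result, numbered 0 with an estimated correlation, 15 with fry, 17 with quantile normalization and 15 after the gene length correction. Among lists not called in the result, calls were gained by fat and mesothelium (no filter, median-of-ratios scaling, quantile normalization, gene length correction and fry), NK cells (quantile normalization, array weights and gene length correction), cholangiocytes (quantile normalization, gene length correction and fry), pericentral, periportal and autophagy genes (quantile normalization and fry), T cells (array weights and gene length correction), erythroid cells (gene length correction and fry), endothelium and p53 targets (fry), innate sensing (array weights), the circadian clock (no filter), and bile acid synthesis and transport (mean of at least 5 FPKM, quantile normalization, gene length correction and fry). Calls gained on leaving out a library are given with the lists above. Fry asks whether a list moves on balance and does not compare it with other genes. In simulated libraries, 4 against 4, 95.5% of 2-fold changes were called but 38.8% of 1.5-fold changes. These shares need not hold in the data, where Alb-Cre replicate 4 stood apart, so an uncalled gene may still differ by 2-fold or more.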

Other observations

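Gene families and genes in these paragraphs were chosen after their values were seen, so the families are described without a test. Of 80 cytosolic ribosomal protein genes 44 were called higher in Alb-Cre livers and none lower, with a median log2 fold change of 0.36, which was 0.26 to 0.47 under other scalings. Their scores were 0.42, 0.16 and 0.46 in Alb-Cre replicates 1 to 3 and 0.45 in replicate 4, but also -0.13, 0.14, -0.14 and 0.13 in the Alb-WT libraries, a swing between replicates of the same genotype. Mitochondrial ribosomal protein genes rose in 25 of 79 cases, with scores of 0.21, 0.14 and 0.23 in Alb-Cre replicates 1 to 3 and 0.17 in replicate 4. Interferon-inducible GTPases fell in 16 of 17 cases, with a median of -1.68 and scores of -2.35, -2.31 and -2.37 in Alb-Cre replicates 1 to 3 and -0.56 in replicate 4. Some of them are also in the interferon list above.

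Major urinary protein rows, near-identical paralogs and so uncertain singly, took 12.5%, 13.2% and 11.5% of all FPKM in Alb-Cre replicates 1 to 3, 2.1% in replicate 4 and 4.4% to 4.5% in Alb-WT. Of 19 rows 8 rose. Immunoglobulin constant genes scored -1.07, -1.01 and -1.12 in Alb-Cre replicates 1 to 3 and 1.57 in replicate 4: Ighg2c was 60.2 FPKM in replicate 4, 1.24, 1.31 and 0.57 in the other Alb-Cre libraries and 5.34 ± 0.932 in Alb-WT (SD, n = 4). The metallothionein gene Mt1, which did not pass the test, was 1680 FPKM in replicate 4 and 154, 139 and 160.0 in the others, against 523 ± 75.1 in Alb-WT. Without replicate 4, Ighg2c and Mt1 were called lower (log2 fold changes -1.65 and -1.77, adjusted p = 5.7e-06 and 1.83e-07). Serum amyloid genes Saa1 (1.16) and Saa2 (1.47) rose on the log2 scale (adjusted p = 0.0318 and 0.0363, and 0.053 for both adjusted over their list alone). Alb-Cre replicate 4 had 4450 and 5090 FPKM of them, against 1630, 1320 and 1560 FPKM of Saa1 and 1200, 1070 and 1210 FPKM of Saa2 in the others. Without it the log2 fold changes were 0.77 and 0.93 (adjusted p = 1.75e-05 and 6.69e-07), and both calls were lost on leaving out Alb-Cre replicate 1 (adjusted p = 0.0575 and 0.0569) or 3 (0.0549 and 0.0586), or any Alb-WT library (0.0619 to 0.0797 and 0.0721 to 0.0869). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell to 5.79 ± 3.37 from 26.8 ± 1.5 FPKM, and Cyp2b10, a drug-metabolising enzyme, to 1.79 ± 0.462 from 12.6 ± 1.18. H19, an imprinted noncoding RNA, rose to 2.01 ± 0.371 from 0.0991 ± 0.0318, and Esm1, an endothelial proteoglycan gene, fell to 0.372 ± 0.0973 from 4.05 ± 0.519 FPKM. The 13 mitochondrially encoded genes, found under other symbols, took 9.4% to 11.5% of FPKM in Alb-Cre and 11.1% to 12.2% in Alb-WT.

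Deviations of each library from the Alb-WT mean followed gene length to a degree. Across 11069 genes, which are not independent replicates, Spearman's rho with length was -0.23, -0.18, -0.26 and -0.18 in Alb-Cre replicates 1 to 4 and 0.15, -0.11, 0.21 and -0.25 in Alb-WT replicates 1 to 4. The shift of long genes was largest in Alb-Cre replicates 1 to 3. For genes over 8000 bp the median log2 deviation was -0.247, -0.253, -0.248 and -0.058 in Alb-Cre replicates 1 to 4. It was 0.021, -0.015, 0.03 and -0.032 in Alb-WT replicates 1 to 4. Small falls of long genes cannot be told apart from this trend, whose cause was not tested.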
